A study of Mus musculus with 6 samples.

How the data were processed

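Total RNA of splenic germinal centre B cells from 6 mice was labelled with biotin by a 3' in vitro transcription kit and hybridised to Affymetrix mouse 430 2.0 arrays, per the labels' protocols. The design text gives 3 mice of each genotype, so the arrays of a group were treated as separate animals. The deposited values are log2 expression levels, 1 per probe set and array, and were made with RMA, with Partek also named, per the submitters' processing notes; versions and settings were not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a set on the log2 scale, which compresses differences of dim probe sets. The deposited log2 values ran from 2.16 to 15.1 and had close medians without identical distributions, and no detection calls came with them.

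Probe sets were named through GEO's platform annotation, updated through the Entrez identifier with a RefSeq gene table of assembly GRCm38.p6, which 18033 of the tested genes matched and which changed 0 symbols. Of 45101 probe sets, 34945 had exactly 1 gene symbol, 932 had several and were left unnamed, and 9211 had none in the table. The 64 Affymetrix controls were not used: 51 of them are among the 9211, and the other 13, which have a symbol, are in none of these counts. Each of 18193 genes was represented by its probe set of highest mean over the 6 arrays, with no filter on dim probe sets. Coordinates are not given because no genome build was named for the arrays.

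Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are ImHABCL6/Uchl1 minus control on the log2 scale. Single values such as probe set levels and list scores were also compared with exact two-sided permutation tests, whose smallest p is 0.1 with 3 arrays against 3. The replicate numbers of the labels are not stated to pair mice, so no block was used.

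Before the data were examined, 41 gene lists with 950 genes were written for germinal centre and B-cell programmes, BCL6, ubiquitin, AKT, mTOR and translation, metabolism, stress, and markers of other cell types, and 857 of these genes were measured. The 40 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry beside it, and each list's members were also adjusted over the list alone. No correction across lists was made for the adjustment over the list alone, so some such passes can arise by chance. The immunoglobulin constant list had 3 measured members and was not tested. The choice of named genes was fixed at the same time: Uchl1 and Bcl6, the 12 genes of each direction with the largest change among those passed and fully separated, filled up with the genes of smallest unadjusted p where too few passed, and up to 4 members of smallest p in each list. Genes without a described name were counted and not named.

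The steps were tested on simulated data for the comparison of ImHABCL6/Uchl1 with control, with 18193 genes and 20 draws. At an adjusted p of 0.05, 4.5% of genes changed by 0.5 on the log2 scale were recovered, 74.3% at 1, 98.8% at 2 and 99.8% at 3, with 9.75 false calls per draw. Over the draws 1000 genes were changed at each size, with independent noise at limma's moderated SDs. Many large changes loosen the adjusted threshold, so these shares can overstate recovery in the real data. There Uchl1 differed by 0.94 with a limma adjusted p of 0.638. Camera at the preset correlation recovered 96.2% of lists shifted by 0.25 and called 0.712% of unshifted lists, where simulated genes were independent. Estimated correlations within the real lists ran from -0.04 (FOXO targets) to 0.89 (megakaryocyte and platelet markers), with 0.10 for G1/S. These list shares therefore do not carry over to the real data.

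Alternatives chosen before the data were examined were the mean of all probe sets per gene and leaving out suffixed probe sets or dim genes. Suffixed probe sets are those whose names end in _x_at, _s_at or _a_at. Others chosen then were 3 further normalizations between arrays, trend and robust options, array weights, a replicate block and all probe sets. Other thresholds, both other list tests and leaving out each array were also chosen then. An erythroid score as a covariate, the mean of the 14 measured erythroid markers per array, was added after the data were seen. Figures were drawn with matplotlib 3.10.9.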

Results

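Germinal centre B cells were prepared with magnetic beads from the spleens of mice immunised with sheep red blood cells, a particulate antigen that induces a strong germinal centre response, and their total RNA was measured on Affymetrix mouse 430 2.0 arrays. Germinal centre B cells are activated B cells that divide rapidly, mutate their immunoglobulin genes and are selected for antigen binding, and BCL6 is the transcriptional repressor that defines them. ImHABCL6 mice express a tagged BCL6 from an immunoglobulin heavy-chain promoter and served as the controls (3 arrays). ImHABCL6/Uchl1 mice carried in addition a transgene for Uchl1, a deubiquitinating enzyme best known from neurons (3 arrays). The comparison asked how the Uchl1 transgene alters the transcriptome of these cells. The deposited values were log2 expression levels of 45101 probe sets, and the medians of the 6 arrays lay between 5.56 and 5.67. Pearson correlations between arrays, across the 18193 genes tested, ranged from 0.979 to 0.995, and genes are not independent replicates in such a correlation. The first principal component (45.5% of variance) did not follow genotype. Control replicate 1 (-19.5) lay with ImHABCL6/Uchl1 replicates 1 (-32.1) and 3 (-12.7), and the remaining arrays lay at 7.96 to 36.7. The second (22.7%) separated the groups, with controls at 13.7 to 18.7 and ImHABCL6/Uchl1 at -23.6 to -3.63. The number of arrays, 3 per group, limits the precision of every difference below.

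Uchl1 itself was higher in every ImHABCL6/Uchl1 array than in every control, whereas Bcl6, deregulated in both genotypes, overlapped between them. The probe set for Uchl1 (1448260_at) read at most 5.02 in the controls and 5.96, 5.87 and 6.02 in the ImHABCL6/Uchl1 arrays, or 5.01 ± 0.01 against 5.95 ± 0.08 (SD, n = 3 each), a 1.92-fold difference. The main Bcl6 probe set (1421818_at) was bright in both groups, at 11.14 ± 0.09 in controls and 11.38 ± 0.23 in ImHABCL6/Uchl1 cells (SD, n = 3 each).

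The log2 difference of Uchl1 was 0.94 with a standard error of 0.12, the smallest unadjusted p of all genes in limma's moderated test (5.29e-05), although the Benjamini-Hochberg adjusted p over 18193 genes was 0.638. An exact two-sided permutation test of the 6 Uchl1 values gave p = 0.1, the smallest that 3 arrays against 3 allow. The Uchl1 signal was dim, and the filter on dim genes removed it. Which part of the Uchl1 transcript the transgene carries was not given in the sources used here, so the probe set can understate the transgene. Bcl6 differed by 0.24 on the log2 scale (SE 0.15, limma adjusted p = 0.998, exact permutation p = 0.2). Its other probe set (1450381_a_at) read 8.16 ± 0.11 and 8.18 ± 0.31 (SD, n = 3 each). The Bcl6 difference was 0.12 without ImHABCL6/Uchl1 replicate 1 and 0.07 with array weights.

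**Figure D1:**
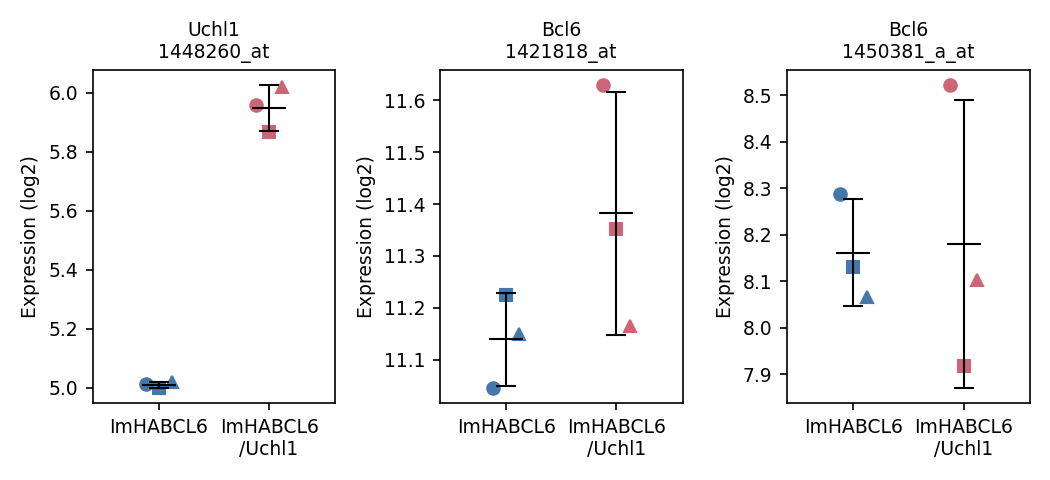
Log2 expression of Uchl1 (1 probe set) and Bcl6 (both probe sets) on each array, controls in blue and ImHABCL6/Uchl1 in red, with replicate 1 as a circle, replicate 2 as a square and replicate 3 as a triangle; bars show the mean and SD of 3 arrays, and the vertical axes differ and do not start at 0. Uchl1 lay between 5.87 and 6.02 in the ImHABCL6/Uchl1 arrays and at 5.02 or less in the controls, while both Bcl6 probe sets overlapped between the groups.

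Beyond Uchl1, the genes of smallest p that were higher with the transgene included the follicular B-cell receptor Fcer2a (CD23), the histone deacetylase Hdac9, the chromatin remodeller Chd7 and the microtubule-bound ubiquitin ligase Mid1. Those lower included Septin8, a cytoskeletal GTPase, Hnrnpll, a regulator of alternative splicing in lymphocytes, Slc39a8, a zinc importer, and Lpin1, a phosphatidate phosphatase. None of them passed the multiple-testing threshold, and no gene did. Most of the large differences were downward, with 162 genes at least 2-fold lower in ImHABCL6/Uchl1 cells and 7 at least 2-fold higher.

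With limma, 0 of 18193 genes had an adjusted p under 0.05 or under 0.10, and 898 had an unadjusted p under 0.05, where chance alone gives 910. Of these 898 genes 700 were lower and 198 higher, or 78% lower. That share was 87.9% when arrays were centred on their medians (820 lower, 113 higher), 87.4% without dim genes (557 and 80), 57.7% after quantile normalization (530 and 389) and 63.7% with array weights (1797 and 1022). The 3 arrays of one group all lay above those of the other for 1717 genes, which is 9.44% of genes, and chance gives 10%. The median standard error of a log2 difference was 0.165. Of the 162 genes 8 were erythroid markers. The numbers of genes at least 2-fold lower and higher moved with single arrays, to 58 and 10 without ImHABCL6/Uchl1 replicate 1, 285 and 13 without its replicate 2, 261 and 14 without control replicate 1 and 92 and 4 without control replicate 3, and they were 65 and 34 with the erythroid score as a covariate, 171 and 29 with array weights and 108 and 4 with the mean of all probe sets.

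The 12 genes per direction that a fixed rule named all separated the groups completely without passing the threshold (limma adjusted p from 0.638 to 0.854). They were picked for smallest p, so this separation follows largely from the choice. Among the higher genes, Mid1 differed by 1.01 (SE 0.26), the kinase anchor Akap2 by 0.90 (SE 0.21), the chemokine Ccl6 by 0.75 (SE 0.19) and Chd7 by 0.62 (SE 0.17). Fcer2a differed by 0.57 (SE 0.14), from 9.88 ± 0.08 to 10.46 ± 0.18 (SD, n = 3 each). Hdac9 differed by 0.49 (SE 0.12), the kinase Sbk1 by 0.60, Ccdc122 by 0.58, the phosphodiesterase Smpdl3b by 0.50 and the vomeronasal receptor Vmn2r84 by 0.63. Tubb2a-ps2, a tubulin pseudogene whose sequence resembles expressed tubulins, differed by 0.55 and is uncertain for that reason. On the lower side, Sh3d19 differed by -1.45 (SE 0.24), Pdia2, a protein disulphide isomerase, by -1.36 (SE 0.23), Slc39a8 by -1.29 (SE 0.23) and Septin8 by -1.25 (SE 0.19). Hnrnpll differed by -1.19, the chloride channel Clcn2 by -1.17, the fatty acid dehydratase Hacd1 by -1.12, the actin nucleator Jmy by -1.08 and Klhl23 by -0.97. Purg differed by -0.91, the SH2-domain protein Sh2d4a by -0.86 (SE 0.13) and Lpin1 by -0.68 (SE 0.12). The size depended on the probe set for several genes: averaging all probe sets of a gene gave 0.50 for Mid1, 0.37 for Ccl6, 0.18 for Tubb2a-ps2, -0.65 for Septin8, -0.58 for Purg, -0.48 for Sh3d19, -0.48 for Jmy and -0.79 for Slc39a8. Array weights gave 0.55 for Akap2, and without suffixed probe sets Sbk1 gave 0.33 and Sh3d19 -0.11. Ccl6, Smpdl3b, Vmn2r84, Tubb2a-ps2 and Clcn2 were read by dim probe sets, which the filter on dim genes removed, and their differences are less certain for that reason.

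**Figure D2:**
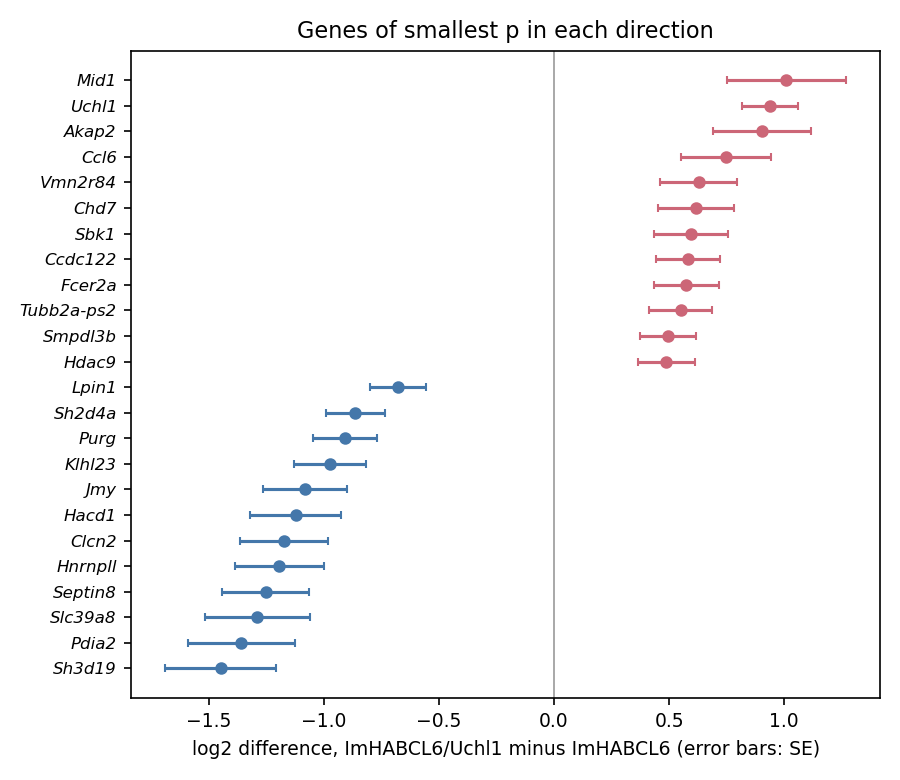
Log2 difference of the 12 genes of smallest p in each direction, ImHABCL6/Uchl1 minus control, with bars of 1 standard error from limma; red marks higher and blue lower genes. Differences ran from -1.45 (Sh3d19) to 1.01 (Mid1), and none passed the adjusted threshold.

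Genes of the cell division cycle were lower in ImHABCL6/Uchl1 cells almost without exception, by small amounts. Of the G1/S and DNA replication genes 36 of 36 measured were lower, with a median log2 difference of -0.23, or 1.18-fold, and of the G2/M and mitosis genes 38 of 39 were lower, with a median of -0.21. The replication licensing factor Cdc6 (-0.69, SE 0.13), cyclin E2 (Ccne2, -0.72, SE 0.17), the replicative helicase subunit Gins1 (-0.45, SE 0.13) and thymidine kinase (Tk1, -0.40, SE 0.12) led the first list. Anillin (Anln, -0.77, SE 0.22), the centromeric histone Cenpa (-0.42, SE 0.13) and the spindle proteins Tpx2 (-0.38) and Prc1 (-0.36) led the second. Genes of DNA damage response and repair followed, 31 of 35 lower with a median of -0.17, among them Bard1 (-0.59, SE 0.16), Brca1 (-0.47, SE 0.13), Blm (-0.41) and Fanci (-0.35).

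No member of these lists passed over all genes; adjusted over the list alone, 1 of the 36 G1/S genes passed (Cdc6, adjusted p = 0.0281 in limma), and 0 of 39 and 0 of 35 in the other lists. Camera with a preset inter-gene correlation called G1/S (adjusted p = 8.3e-14), G2/M (8.33e-10) and DNA damage (8.32e-07). None of the 3 calls held with an estimated correlation, where the adjusted p was 0.515 for G1/S, 0.827 for G2/M and 0.827 for DNA damage. Fry, which asks whether the genes of a set move on balance one way, gave G1/S an unadjusted p of 0.00317 and an adjusted p of 0.127, and its test for change in either direction gave G1/S an adjusted p of 0.0109. The mean score of the G1/S genes was 0.13, 0.10 and 0.18 in the controls and -0.12, -0.21 and -0.08 in the ImHABCL6/Uchl1 arrays, an exact permutation p of 0.1. G2/M scores also lay apart, at -0.01, 0.11 and 0.23 against -0.04, -0.11 and -0.18 (exact permutation p = 0.1). DNA damage scores overlapped, at 0.13, 0.11 and 0.07 in the controls and 0.11, -0.22 and -0.20 in the ImHABCL6/Uchl1 arrays, so that replicate 1 of the transgenic group lay within the controls (exact permutation p = 0.2). Without that array, which had the lowest erythroid signal, the DNA damage median was -0.31, and with the erythroid covariate it was -0.38. Leaving out ImHABCL6/Uchl1 replicate 2 left 24 of the 35 DNA damage genes lower, and leaving out its replicate 3 left 27. The G2/M median was -0.12 after quantile normalization. Single genes moved as well: the mean of all probe sets gave -0.15 for Cenpa, -0.18 for Tpx2 and -0.20 for Fanci, and the erythroid covariate gave -0.44 for Anln and -0.19 for Prc1.

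**Figure D3:**
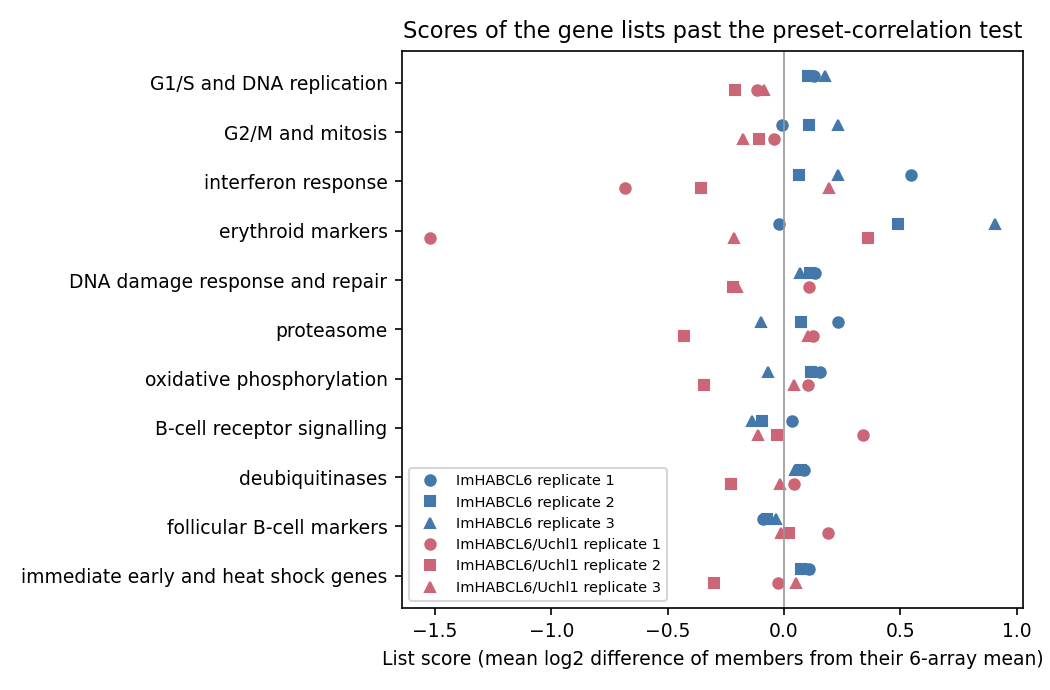
Score of each array for the 11 gene lists called by camera with the preset correlation, as the mean log2 difference of the list's genes from their 6-array means; controls in blue, ImHABCL6/Uchl1 in red, with replicates 1, 2 and 3 as circles, squares and triangles. G1/S scores separated the groups (0.10 to 0.18 against -0.21 to -0.08), whereas erythroid scores ranged from -1.52 to 0.91 and overlapped.

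Interferon-stimulated genes were lower by larger amounts and less evenly between mice. Of 29 measured genes 27 were lower in ImHABCL6/Uchl1 cells, with a median log2 difference of -0.49, or 1.41-fold. Irf9, a subunit of the interferon-activated factor ISGF3, differed by -0.66 (SE 0.16), the master regulator Irf7 by -0.60 (SE 0.16), the RNA sensor Ifih1 by -1.42 (SE 0.36) and the GTPase Igtp by -1.46 (SE 0.47). Scores were 0.55, 0.07 and 0.23 in the controls and -0.69, -0.36 and 0.20 in the ImHABCL6/Uchl1 arrays, so that replicate 3 of the transgenic group lay within the controls (exact permutation p = 0.2). Replicate 1, of the lowest interferon score, also had the lowest erythroid mean of all arrays, 9.17. Camera called the list with the preset correlation (adjusted p = 8.33e-10), not with an estimated one (adjusted p = 0.827), and with array weights the preset test gave an adjusted p of 0.0609 and a median of -0.20, with Ifih1 at -0.86 and Igtp at -0.76. Irf9, Ifih1 and Irf7 passed when adjusted over the list alone (each with a limma adjusted p of 0.0469), and 0 genes did over all genes.

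Transcripts of red-cell precursors were detected on all arrays, at high levels that varied between mice and were lower on average with the transgene. The 14 measured erythroid markers averaged 11.15 ± 0.46 in controls and 10.24 ± 0.96 in ImHABCL6/Uchl1 arrays (SD, n = 3 each), a difference within the spread between arrays (exact permutation p = 0.2). Slc4a1, the anion exchanger of red cells, had a mean of 13.4 over the 6 arrays, above 99.6% of genes. The median erythroid marker lay above 95.7% of genes, close to the 96.2% of germinal centre identity genes. For the other lists of non-B cells this share ran from 23.2% (NK cells) to 70.9% (megakaryocytes and platelets). Group differences can therefore reflect the whole preparation and not B cells alone. The erythroid regulators Klf1 (-1.30, SE 0.45) and Gata1 (-1.10, SE 0.38), the erythropoietin receptor Epor (-1.02) and carbonic anhydrase Car1 (-0.86, SE 0.24) had the smallest p of the list. Of the 14 genes 13 were lower, with a median log2 difference of -1.03 (camera adjusted p = 2.82e-08 with the preset and 0.85 with an estimated correlation). None passed over all genes or adjusted over the list alone. The mean was lowest, 9.17, in ImHABCL6/Uchl1 replicate 1, and without that array the median difference was -0.56, with Klf1 at -0.73, Gata1 at -0.62, Epor at -0.66 and Car1 at -0.56.

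**Figure D4:**
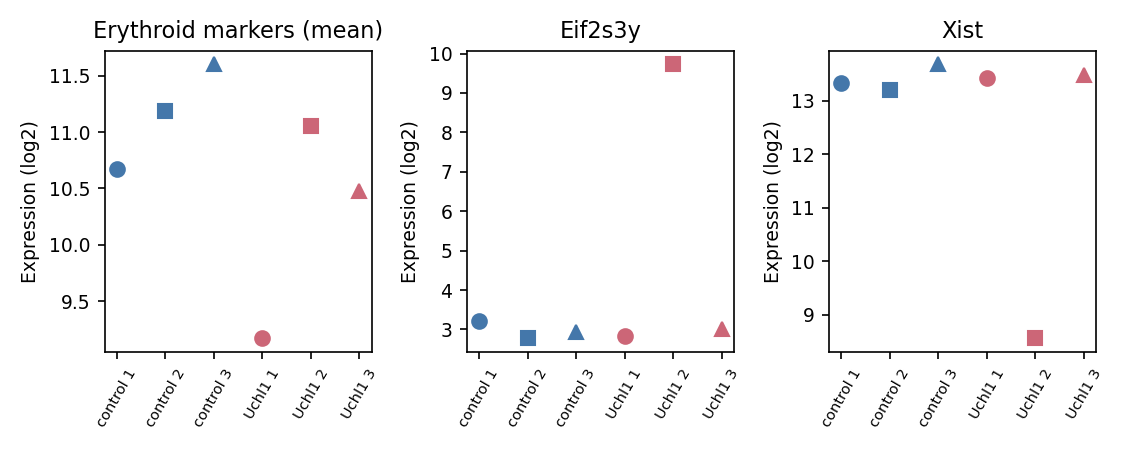
Mean log2 level of 14 erythroid markers, and the levels of the Y-linked gene Eif2s3y and of Xist, on each array; controls in blue, ImHABCL6/Uchl1 in red. Erythroid means ran from 9.17 to 11.6, and ImHABCL6/Uchl1 replicate 2 alone had Eif2s3y at 9.72 and Xist at 8.56.

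Deubiquitinases, the enzyme class of Uchl1, were lower in 35 of 51 cases with a median of -0.14, led by Josd2 (-0.71, SE 0.23), the interferon-induced Usp18 (-1.14, SE 0.37) and Otud5 (-0.44, SE 0.17), whereas Usp2 was higher (0.38, SE 0.16). Proteasome subunits were lower in 36 of 37 cases (median -0.13, for example Psmc6 at -0.29 and Psmc3 at -0.25), oxidative phosphorylation genes in 34 of 42 (median -0.13, for example Ndufb9 at -0.37 and Atp5b at -0.28), and immediate early and heat shock genes in 18 of 25 (median -0.16). The last list was led by the phosphatase Dusp1 (-0.67, SE 0.19) and the chaperones Hspa1b (-1.02), Dnaja1 (-0.58) and Hsph1 (-0.66). Camera with the preset correlation called all 4 lists (adjusted p = 0.0146, 0.00724, 0.00897 and 0.0367), and with an estimated correlation each had an adjusted p of 0.85. No member passed over all genes or adjusted over the list alone. The sizes moved both ways with the setting. Without ImHABCL6/Uchl1 replicate 2 the medians were -0.03 for deubiquitinases, 0.05 for the proteasome, 0.01 for oxidative phosphorylation and -0.06 for heat shock genes, and without control replicate 1 they were -0.09, -0.06, -0.08 and -0.16, with no camera call in any case. Without any 1 of the other 4 arrays the first 3 lists kept the call. The erythroid covariate gave larger medians of -0.25 for deubiquitinases, -0.41 for the proteasome and -0.33 for oxidative phosphorylation (camera adjusted p = 0.00139, 2.74e-07 and 2.28e-06), and -0.26 without a call for heat shock genes (0.0873). With array weights none of the 4 was called either (adjusted p = 0.189, 0.858, 0.976 and 0.636). Leaving out ImHABCL6/Uchl1 replicate 2 put Psmc3 at -0.08, Atp5b at -0.10, Ndufb9 at -0.20, Dnaja1 at -0.33 and Hsph1 at -0.35, and Usp2 was at 0.26 without control replicate 1. The heat shock list was also not called without control replicate 3 (median -0.12, adjusted p = 0.0974) or ImHABCL6/Uchl1 replicate 1 (-0.19, adjusted p = 0.0566), the latter with a median no smaller than that of all arrays. Array weights gave -0.39 for Josd2 and -0.52 for Usp18, and the erythroid covariate -0.22 for Otud5, -0.45 for Psmc3 and -0.47 for Atp5b.

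Genes of the follicular B cell and of B-cell receptor signalling leaned upward. Follicular markers were higher in 10 of 13 cases (median 0.13), led by Fcer2a and with Ccr6 at 0.47 (SE 0.22) and Bcl2 at 0.36 (SE 0.16), while Cd55 was lower at -0.46. B-cell receptor signalling genes were higher in 21 of 26 cases (median 0.10), led by the complement receptor Cr2 (0.62, SE 0.28), Malt1 (0.35), Bank1 (0.31) and Pik3cd (0.22). Camera with the preset correlation called both (adjusted p = 0.0231 and 0.0129), and neither held with an estimated correlation (adjusted p = 0.827 and 0.85). Fcer2a passed when adjusted over the list alone (limma adjusted p = 0.0467), as the 1 gene of 13, and 0 of the 26 receptor signalling genes did. Without ImHABCL6/Uchl1 replicate 1 the medians were 0.04 and -0.04, and neither list was called (camera adjusted p = 0.235 and 0.948). Without control replicate 2 neither was called (adjusted p = 0.0764 for both), nor the follicular list without control replicate 1 (adjusted p = 0.0861), but the medians stayed close to those of all arrays, at 0.12 and 0.09 and at 0.11. With the erythroid score as a covariate, a setting chosen after the data were seen, the medians were 0.01 for follicular markers and -0.08 for receptor signalling (camera adjusted p = 0.281 and 0.547), and with array weights 0.12 and 0.0049 (adjusted p = 0.151 and 0.608). Single genes moved both ways: Cr2 was at 0.39 and Bank1 at 0.12 without ImHABCL6/Uchl1 replicate 1, but at 0.95 and 0.48 without its replicate 3. Malt1 was at 0.17 without control replicate 2 and at 0.55 without control replicate 3. Without control replicate 3 Cd55 was at -0.30 and Pik3cd at 0.14. Array weights gave 0.11 for Cr2, 0.06 for Bank1, 0.19 for Ccr6 and 0.24 for Bcl2, and the mean of all probe sets 0.07 for Pik3cd.

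No list of the germinal centre programme itself was called with all 6 arrays in the main fit, although several were under alternatives. Of 24 germinal centre identity genes 15 were higher and 9 lower (camera adjusted p = 0.161), led by the B-cell transcription factors Bach2 (0.47, SE 0.13), Pax5 (0.48, SE 0.17), Mef2c (0.42, SE 0.16) and Ebf1 (0.55, SE 0.22). Camera adjusted p was 0.28 for the dark zone list, 0.399 for the light zone, 0.722 for targets repressed by BCL6, 0.549 for plasma cell differentiation, 0.133 for class switching and somatic hypermutation and 0.0761 for migration and positioning, where S1pr3 (0.39) and Efnb1 (0.31) led. Without ImHABCL6/Uchl1 replicate 2, camera called 4 of these lists upward: germinal centre identity (median 0.16, adjusted p = 0.0103), light zone (0.23, adjusted p = 0.00188), plasma cell differentiation (0.16, adjusted p = 0.019) and migration (0.17, adjusted p = 0.00616). Identity and migration were also called upward after quantile normalization (adjusted p = 0.0253 and 0.00757) and cyclic loess (adjusted p = 0.0103 and 0.00778), and migration without dim genes (adjusted p = 0.0154) and without control replicate 3 (adjusted p = 0.0322). The light zone was called upward without control replicate 1 (0.17, adjusted p = 0.0229) and downward with the erythroid covariate (-0.28, adjusted p = 0.031). Class switching was called downward with that covariate (-0.28, adjusted p = 0.00286) and without ImHABCL6/Uchl1 replicate 1 (-0.24, adjusted p = 0.0027). The dark zone list and the targets repressed by BCL6 were called under 0 of 18 alternatives. Among single genes, the erythroid covariate gave 0.19 for Ebf1 and 0.21 for Mef2c. Array weights gave 0.35 for Ebf1, and leaving out suffixed probe sets gave 0.20 for S1pr3. No gene of these lists passed over all genes or adjusted over the list alone.

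Earlier work on lymphoid cells linked Uchl1 to AKT and mTOR signalling and to the assembly of the translation initiation complex. The lists of components of these pathways showed no call in the main fit, and for translation this depended on single arrays. Transcript levels of components do not measure signalling or complex assembly, so these lists do not test that work. Among the 33 components of PI3K, AKT and mTOR 19 were lower and 14 higher (camera adjusted p = 0.476), with the catalytic subunits Pik3cb at -0.60 (SE 0.17) and Pik3cg at 0.50 (SE 0.15), and the phosphatase Phlpp2 at -0.36. Translation initiation genes were lower in 28 of 36 cases (camera adjusted p = 0.154), with the cap-binding protein Eif4e at -0.40 (SE 0.22), its kinase Mknk1 at -0.45 (SE 0.17) and its inhibitor Eif4ebp1 at -0.23 (SE 0.15). Without ImHABCL6/Uchl1 replicate 2 Eif4e was at -0.15 and Eif4ebp1 at -0.12, and the mean of all its probe sets put Mknk1 at -0.13. For MYC targets and ribosome biogenesis the adjusted p was 0.154, with Odc1 at -0.37 and Nop56 at -0.30, and Tfrc (-0.96) also belongs to the erythroid list. It was 0.184 for ribosomal proteins, 0.622 for FOXO targets, 0.476 for p53 targets, with Sesn1 of both at -0.66 (SE 0.18), 0.889 for NF-kB targets and 0.889 for apoptosis regulators. Camera called translation initiation lower under 4 of 18 alternatives: without control replicate 3 (adjusted p = 0.0322), ImHABCL6/Uchl1 replicate 1 (0.0067) or its replicate 3 (0.00662), and with the erythroid covariate (9.46e-05). Under the same 4 it called ribosomal proteins lower (adjusted p = 0.0479, 0.0352, 0.0369 and 0.00176) and MYC targets lower (adjusted p = 0.0064, 0.00493, 0.00152 and 2.74e-07), whereas without ImHABCL6/Uchl1 replicate 2 it called MYC targets higher (median 0.18, adjusted p = 0.00632). PI3K, FOXO targets, p53 targets, NF-kB targets and apoptosis regulators were called under 0 of 18. Nop56 was at -0.17 without ImHABCL6/Uchl1 replicate 2, and Tfrc at -0.56 without replicate 1. The erythroid covariate gave -0.65 for Eif4e, -0.19 for Odc1, -0.58 for Nop56 and -0.24 for Tfrc, array weights -0.39 for Pik3cb, and the mean of all probe sets -0.17 for Phlpp2. None of these members passed over all genes or adjusted over the list alone. Median and mean differed in sign for FOXO targets, NF-kB targets and apoptosis regulators.

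Over the 40 lists tested, camera with the preset correlation called 11, of which 9 were lower and 2 higher, and 0 were called with an estimated correlation (smallest adjusted p = 0.515, 1 list at an unadjusted p under 0.05) or by fry's directional test (smallest adjusted p = 0.127, 1 list at an unadjusted p under 0.05). RNA quality differed by less than the spread between arrays: the 3' minus 5' log2 difference of Gapdh was 1.45 ± 0.28 in controls and 1.46 ± 0.42 in ImHABCL6/Uchl1 arrays, and that of Actb 0.93 ± 0.12 and 0.84 ± 0.16 (SD, n = 3 each; exact permutation p = 1.0 and 0.4). Single arrays differed more: Gapdh was highest in ImHABCL6/Uchl1 replicate 2, at 1.94 against 1.21 and 1.22 in replicates 1 and 3 of its group. Its Actb difference was 1.03 against 0.72 and 0.79. Control replicate 3 was close to it, at 1.76 for Gapdh and 1.04 for Actb. ImHABCL6/Uchl1 replicate 2 also had the Y-linked transcript Eif2s3y at 9.72, against at most 3.21 on the other arrays, and Xist at 8.56, against at least 13.2. The 6 sex-linked genes listed, of which 5 were measured, gave a camera adjusted p of 0.399. Xist (-1.58) and Eif2s3y (2.21) moved in opposite directions, so this directional test cannot show whether sex is balanced. The levels per array show that it was not, since only ImHABCL6/Uchl1 replicate 2 had the male pattern.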

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

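The erythroid covariate was chosen after the data were seen, and all other settings before. No gene passed the threshold under any of the 19 alternatives to the limma fit, the looser threshold of 0.10 and the test of all probe sets included. Uchl1 kept its direction under all 15 that measured it, with log2 differences from 0.89 to 0.99 and adjusted p from 0.0689 (array weights) to 1, and had no value without dim genes. Bcl6 kept its direction under 16, from 0.07 to 0.35. The 96 other named genes kept their direction and stayed short of the threshold under every alternative that gave them a value. Without suffixed probe sets 13 had no value, and 5 had none without dim genes. These genes were picked from the same arrays for small p, so a kept direction is partly built in. Leaving out 1 array cannot reverse a gene that separated the groups completely, Uchl1 included, where the same probe set is read. Of the 96, 32 moved by over 1.5 times without 1 array and 60 under another alternative, among them 27 with the erythroid covariate, 26 with array weights and 20 with the mean of all probe sets. Genes at an unadjusted p under 0.05 numbered 2819 with array weights, 2793 with the erythroid covariate and 387 (without control replicate 3) to 1332 (without ImHABCL6/Uchl1 replicate 1) when 1 array was left out, against 898. Without control replicate 2 there were 493. The count of called lists, 11, was 7 without suffixed probe sets, 7 with array weights and 8 to 16 when 1 array was left out. It was 0 with an estimated correlation and 0 by fry's directional test. G1/S, G2/M and DNA damage kept the preset call under all 16 alternatives that kept the preset correlation, the erythroid list under 15 of 15 and interferon under 15 of 16. Medians reversed for B-cell receptor signalling with the erythroid covariate (-0.0766), and without single arrays, where they ranged from -0.035 (without ImHABCL6/Uchl1 replicate 1) to 0.20 for B-cell receptor signalling, and without ImHABCL6/Uchl1 replicate 2 to 0.051 from a lowest of -0.23 for the proteasome and to 0.0139 from -0.21 for oxidative phosphorylation. The cause was not tested. Over all called lists and alternatives, 59 values lost the call with their direction kept and 4 reversed, also uncalled. Of the 29 uncalled lists 14 gained a call in at least 1 alternative, 43 values in all. Same-numbered arrays did not all deviate together (r = 0.43 and 0.19 for numbers 1 and 2, and -0.26 for 3), and not every array correlated best with its own number (control replicate 3 with ImHABCL6/Uchl1 replicate 2, 0.53), so the numbers were not taken as pairs. The replicate block gave 0 genes, 1002 at an unadjusted p under 0.05 and 11 called lists, and changed no call. Dim probe sets, Uchl1 among them, are compressed by background and carry little room for a lower value.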

Other observations

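The unfolded protein response list was not called (18 of 28 lower, camera adjusted p = 0.154). Its members of smallest p, Ddit3 (-0.67, SE 0.15), Atf4 (-0.39, SE 0.13) and asparagine synthetase (Asns, -0.72, SE 0.29), passed neither over all genes nor over the list alone, and Asns was at -0.44 without ImHABCL6/Uchl1 replicate 1 and at -0.21 with array weights, and Ddit3 at -0.41 with the mean of all probe sets. The list was called lower without control replicate 2 (adjusted p = 0.0181), without ImHABCL6/Uchl1 replicate 3 (0.000252) and with the erythroid covariate (0.0235). In the list of glycolysis and hypoxia (camera adjusted p = 0.517), phosphofructokinase Pfkm was at -0.76 (SE 0.16) and passed when adjusted over the list alone (limma adjusted p = 0.035), not over all genes (0.709). The lactate transporter Slc16a1 was at -0.80 and hexokinase Hk1 at -0.59, or -0.52 without control replicate 3 and -0.36 without ImHABCL6/Uchl1 replicate 1, and -0.28 and -0.22 with the erythroid covariate. That list was called lower without ImHABCL6/Uchl1 replicate 3 (adjusted p = 0.00377) and higher with array weights (0.0431). Igha, the constant region of IgA, was at -0.97 (SE 0.48), and at -0.39 without ImHABCL6/Uchl1 replicate 2 and -1.47 without its replicate 1, and -1.89 with the erythroid covariate. MHC class II presentation (camera adjusted p = 0.161) and chromatin regulators mutated in lymphoma (0.795, with the test and the median of opposite sign) were not called. MHC class II was called higher under 5 alternatives, among them without control replicate 1 (adjusted p = 0.0133) and without ImHABCL6/Uchl1 replicate 2 (0.000801).

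Markers of other blood and tissue cells were not called in the main fit either: camera adjusted p was 0.164 for monocytes and macrophages, 0.517 for neutrophils, 0.63 for dendritic cells, 0.549 for NK cells, 0.754 for T cells, 0.754 for megakaryocytes and platelets, 0.295 for marginal zone B cells, 0.549 for stroma and 0.553 for endothelium. Without ImHABCL6/Uchl1 replicate 1 camera called megakaryocyte (adjusted p = 0.00258), stromal (0.0312) and monocyte markers (0.0381) higher, and the other lists were called under no alternative. The erythroid covariate also called the first 2 (0.000346 and 0.0356) and array weights the last (0.0431). The lysozymes Lyz1 (1.27, SE 0.66) and Lyz2 (1.14, SE 0.60) moved with ImHABCL6/Uchl1 replicate 3, where Lyz2 was at 10.6 against 7.30 to 8.89 elsewhere; without it they were at 0.57 and 0.46, and Lyz1 was at 0.77 without control replicate 3. Lyz1 was at 0.13 without suffixed probe sets, and array weights gave 2.30 for Lyz1 and 2.14 for Lyz2. The iron exporter Slc40a1 was at -1.01 (SE 0.31), or -0.62 without ImHABCL6/Uchl1 replicate 1 and -0.45 with the erythroid covariate, and the dendritic cell receptor Flt3 at 0.52 (SE 0.17), or 0.28 with array weights, and none of these passed a threshold.

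The tests below were chosen after the results were seen, apart from the splits of the arrays. The criteria for the slopes on the erythroid score were written before those slopes were seen, but the genes they cover were picked from these results.

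More genes were at least 2-fold lower (162) than higher (7), and fewer erythroid cells in the transgenic preparations are a candidate explanation, since the bead isolation is not described as removing red-cell precursors by name. Of the 162 genes 8 were erythroid markers, and the other 154 followed the erythroid score within groups with a median slope of 0.874 (0.826 to 0.982 when 1 array was left out), against -0.01 for all other genes; 92.9% of the 154 had a positive slope. With the score as a covariate 24 of the 154 stayed at least 2-fold lower. The erythroid mean ranked the arrays of each group as the 3' minus 5' difference of Gapdh did, a measure of RNA quality. Control replicates 1, 2 and 3 had means of 10.7, 11.2 and 11.6 with Gapdh at 1.26, 1.32 and 1.76. ImHABCL6/Uchl1 replicates 1, 3 and 2 had 9.17, 10.5 and 11.1 with 1.21, 1.22 and 1.94. Actb did not rank the controls this way. Slope and covariate therefore cannot separate erythroid content from RNA quality. Further normalizations between arrays did not remove the excess, since lower genes still outnumbered higher ones 19-fold under the one of smallest ratio. They were applied to values that RMA had already normalized, so they cannot test that first step. Of the 14 markers 1, Tfrc, stands in another list and is also made by dividing B cells, and whether the erythroid difference follows the genotype stays open with an exact permutation p of 0.2.

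For the lower G1/S genes the tables argue against the erythroid signal, as the score difference was -0.29 (95% interval -0.48 to -0.11) with the erythroid score as a covariate and -0.27 without. For G2/M the same covariate left it open (-0.21, interval -0.57 to 0.15, against -0.22 without), and for DNA damage the difference was -0.36 (-0.54 to -0.18) against -0.21. The G1/S genes did not rest on the single array with male transcripts, without which the median was -0.20. A larger share of resting follicular B cells, which the higher Fcer2a could suggest, cannot be told apart, because the germinal centre identity score differed by 0.0572 with an interval of -0.28 to 0.40. The genotype, the difference that the design gives, was not tested further as a cause.

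For the lower interferon-stimulated genes the tables argue against any single array as the whole cause, since the median nearest to 0 when 1 was left out was -0.33. With array weights, which change several arrays at once, the median was -0.20 and the call was lost (camera adjusted p = 0.0609). With the erythroid score as a covariate the score difference was -0.43 (95% interval -1.71 to 0.84) against -0.56 without, so fewer erythroid cells cannot be told apart as a cause with 6 arrays. A difference in interferon exposure between mice was not tested.

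The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 898 genes and the highest other 2952, with 4 of the 10, the real one included, at least as large. It gave 11 called lists, with 9 of the 10, the real one included, at least as large and the highest other at 24. It gave 0 genes past the threshold, a count that any split reaches and that tests nothing, and the highest other gave 19. The split that called 19 genes set control replicate 1 and ImHABCL6/Uchl1 replicates 1 and 3 against the rest. It had the largest erythroid difference of the 10 (1.17). It also parted the arrays completely by the 3' minus 5' difference of Gapdh (1.21 to 1.26 against 1.32 to 1.94). It was picked as the highest of the splits, and whether its count exceeds chance was not tested.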
